A study of Caenorhabditis elegans with 6 samples.

How the data were processed

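Total RNA from mixed-stage whole worms, wild-type N2 and outcrossed tdp-1(ok803), was taken up in TRIzol and purified on RNeasy columns, and labelled with biotin by the 3' IVT Express protocol for the Affymetrix C. elegans Genome Array, per the labels' protocols. The series' design text calls the 3 samples of each genotype biological replicates. Samples were grouped by the genotype in their labels. The deposited table holds log2 values, 1 per probe set and array. RMA, which corrects background, normalizes and summarises probes on the log2 scale, and Partek are named in the submitters' processing notes, with no version, and the probe-level settings are not given in the sources used here. That the scale is log2 was read from the values. Array medians were 5.41 to 5.52 and quartiles differed between arrays. Scanner files were not used here, so signal over background was not assessed per probe set.

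Control probe sets (77) were left out of the tests and used only for the 3' and 5' values of actin and Gapdh and for the hybridization spikes. Of 22548 probe sets tested, 20766 carried 1 gene symbol in the platform annotation, 887 several and 895 were not listed. Symbols were updated by gene ID through the WBcel235 gene table, where 65 probe sets with 1 symbol found no match. For each of 17118 genes the probe set with the highest mean over all 6 arrays stood for the gene. No probe set with several symbols was named.

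Differences are tdp-1(ok803) minus wild type, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with fry beside it, with adjustment over the 31 lists of at least 5 measured members. They name 718 genes, 42 of which were not measured, besides the families taken by name, and a gene can stand in more than 1 list, as sod-3, gst-10 and mtl-2 do. Counts adjusted over the list alone adjust the limma p over the list's members. Single values per array were compared by exact permutation, whose smallest two-sided p is 0.1 for 3 against 3.

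Named genes followed a rule fixed before the data were examined: tdp-1, up to 12 genes in each direction with an adjusted p under 0.05 and groups that do not overlap, and at most 4 members of each list with the smallest p, of which the text gives a part. The changed probe set with no gene name falls outside that rule and was chosen after its values were seen, as were the second probe sets of bus-8B and lpr-3 and the neighbours with the largest and smallest difference.

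On simulated values for 22548 probe sets with 200 changed in each of 5 runs, the moderated test recovered 14.3% of 1.5-fold, 84.6% of 2-fold and 99.7% of 4-fold changes, with 53 false among 732 calls. The unmoderated test recovered 35.5% of 4-fold changes. A list shifted by -0.4 was found by camera in 20 of 20 runs, with 0 false lists. The simulated genes vary independently, which real genes of a list do not. The noise was normal, with the moderated spread of each probe set, and held no axis of variation shared between genes. These settings may favour the moderated test, so its recovery on the real arrays may be lower.

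Alternatives were eBayes with trend and robust, an unmoderated model, another quantile normalization, equal array medians, leaving out probe sets under the 30th percentile of mean signal, array weights, the replicate number as a block and leaving out each array. For lists they also included an estimated correlation, fry and the mean of all probe sets per gene, and for the count a threshold of 0.01. A covariate for the 3' minus 5' difference, and a fit of the 3 arrays where it is smaller, were chosen after seeing the data, as was a least squares fit of list means over the 6 arrays on genotype with that covariate, whose 95% intervals are given. A change of sign was counted as reversed where either setting called the result. Figures were drawn with matplotlib 3.10.9.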

Results

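Gene expression was measured in whole Caenorhabditis elegans of mixed stages on 6 arrays, 3 from wild-type N2 worms and 3 from outcrossed worms carrying tdp-1(ok803), a loss-of-function allele of tdp-1. The gene tdp-1 encodes the worm orthologue of the RNA-binding protein TDP-43. The comparison asked which transcripts differ in abundance when tdp-1 function is lost. Each array gave a log2 value for 22548 probe sets after 77 control probe sets were set aside, with array medians between 5.41 and 5.52. Array profiles correlated at 0.98 to 0.993 within a genotype and at 0.973 to 0.992 between genotypes, across probe sets, which are not independent of each other. The number of arrays, 3 per genotype, limits the precision of every difference given here.

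The transcript of tdp-1 (F44G4.4, chromosome II) fell by 3.97 on the log2 scale in the mutant, a 15.6-fold difference (limma adjusted p = 0.000815). The brighter of 2 probe sets averaged 8.98 ± 0.21 in wild type and 5.01 ± 0.40 in tdp-1(ok803) (SD, n = 3 each). The other tdp-1 probe set fell by 3.99 (limma adjusted p = 0.00217). All 3 mutant values lay below all 3 wild-type values for both probe sets, and the exact permutation test of the array values gave p = 0.1, the smallest two-sided p that 3 arrays against 3 allow. The mutant means ranked at the 41.3 and 31.3 percentiles of probe sets, and whether they lay above background was not assessed, so the size of the fold stays open. Where these probe sets lie relative to the deleted segment was not analysed here.

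Beyond tdp-1, 6 genes rose and 4 fell in the mutant. With all 6 arrays and genotype alone, the largest rise was in clec-60, which encodes a C-type lectin-like protein. It rose by 3.30 ± 0.34 on the log2 scale (difference ± SE, limma adjusted p = 0.0286). Its wild-type mean was 5.09 ± 0.69 (SD), and whether that lay above background was not assessed. The aspartyl protease gene asp-12 rose by 2.98 ± 0.16 (limma adjusted p = 0.000815), from 7.94 ± 0.16 to 10.92 ± 0.26 (SD, n = 3). Over 16 alternatives clec-60 ranged from 2.53 to 3.69 and asp-12 from 2.88 to 3.22, so which of them led depended on the fit. The gene ech-9, of the enoyl-CoA hydratase family, rose by 2.44, the insulin-like peptide gene ins-7 by 2.16, B0348.2 by 2.06 and the neprilysin-like metallopeptidase gene nep-14 by 1.63. Their wild-type means were 4.35, 4.76, 5.44 and 5.14, near or below the array medians. Whether these means lay above background was not assessed, so the sizes of these rises stay open. The genes that fell were col-41, a cuticle collagen, at -1.61, lpr-3, a lipocalin-related gene, at -1.57, pugs-2 at -1.55 and bus-8B at -1.35. Apart from asp-12, their adjusted p lay between 0.00822 (ins-7) and 0.0438 (ech-9) in limma, and the mutant values of all 10 genes lay wholly above or wholly below the wild-type values. A probe set that carries no gene name here rose by 2.64 (limma adjusted p = 0.000815).

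Counted as probe sets, 13 changed at an adjusted p under 0.05 in limma, 7 higher and 6 lower in the mutant, and all 13 differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 1571, 808 higher and 763 lower, where chance alone would give 1127. The groups did not overlap in 11.65% of probe sets, where chance gives 10%. Probe sets vary together and the spread of these 2 chance values was not estimated, so neither excess can be judged. A second probe set of bus-8B differed by -0.37 and a second of lpr-3 by -1.31, with limma adjusted p of 0.544 and 0.276. The count moved between 4 and 97 when single arrays were left out (97 without wild-type replicate 2), and an unmoderated linear model called 0 probe sets. The calls of tdp-1 and asp-12 were kept whichever array was left out, while each of the other 9 named genes lost its call in at least 3 of the 6 cases. With an array left out, differences ran from 1.54 to 1.71 for nep-14 and from 2.02 to 2.31 for ins-7, for example. They ran from -1.69 to -1.41 for pugs-2 and from 2.15 to 2.64 for ech-9. Each such fit shares most arrays with the full one, so close values are partly built in and show no stability.

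**Figure D1:**
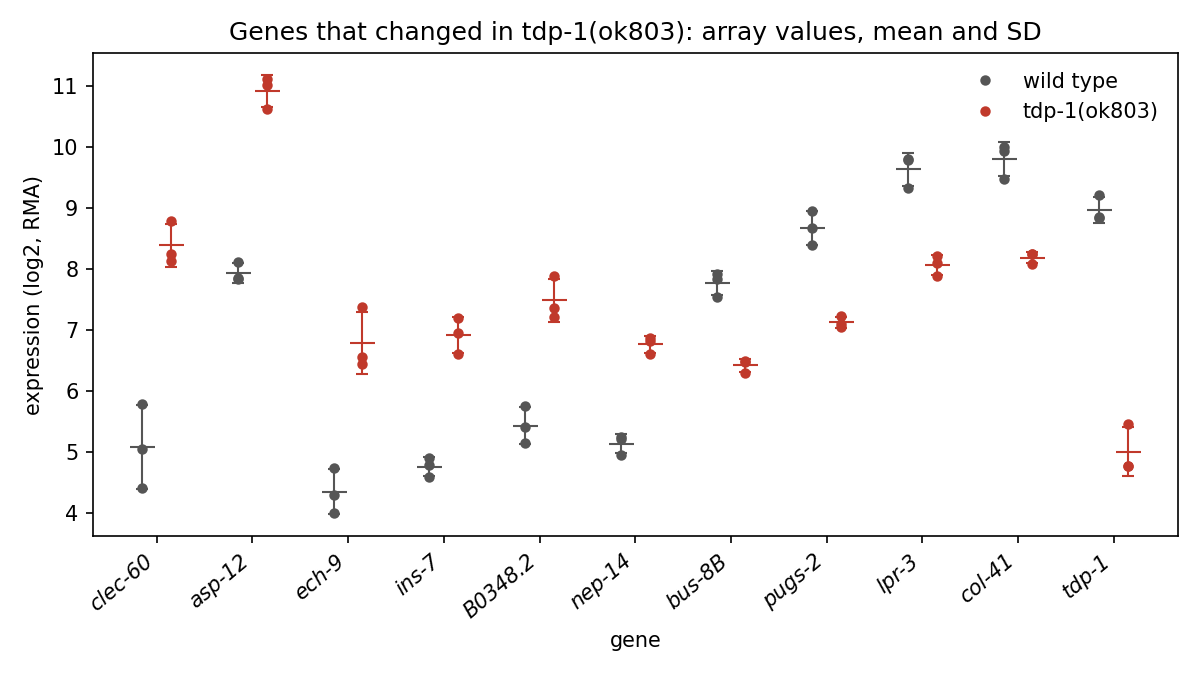
Log2 expression (y axis) of the 11 genes that changed (x axis), in wild type (grey) and tdp-1(ok803) (red); points are single arrays, horizontal marks means and bars SD (n = 3). The groups do not overlap for any of the 11 genes, from clec-60, which rose by 3.30, to tdp-1, which fell by 3.97.

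Arrays also differed along an axis that crossed the genotypes. The difference between the 3' and 5' control probe sets of actin and Gapdh, a sign of RNA integrity and of how far labelling reached from the 3' end, averaged 3.11 ± 0.88 in wild type and 3.80 ± 0.64 in the mutant on the log2 scale (SD, n = 3, exact permutation p = 0.3). It was 2.52 to 3.09 on wild-type replicates 1 and 3 and mutant replicate 2, and 4.01 to 4.31 on the other 3 arrays. The first principal component held 54.3% of the variance and followed this difference over the 6 arrays (Pearson r = 0.973, exact permutation p = 0.00139, adjusted p = 0.00417 over 3 relations; Spearman rho = 1, exact permutation p = 0.00278, adjusted p = 0.00833). Without the 2 arrays farthest from the median, r was 0.931. The second component held 19.2% and placed all mutant arrays above all wild-type arrays (exact permutation p = 0.1). With the 3' minus 5' difference as a covariate, chosen after seeing the data, limma called 25 probe sets, 12 higher and 13 lower, among them 12 of the 13.

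Of 31 gene lists fixed before the data were examined, camera called 10 with its preset correlation of 0.01, 3 upward and 7 downward. Below, falling or rising as a set means being called in this way. As many lists came from 7 of the 10 splits of the arrays into 3 and 3, the real split included. Mutant list means lay wholly above or below the wild-type ones for moulting, innate immune effectors and neuron genes, and overlapped for the other called lists. With the correlation estimated per list, camera called 0 of the 31 (smallest adjusted p = 0.453), and 2 lists, moulting and innate immune effectors, had an unadjusted p under 0.05. The directional test of fry also called 0, with 3 lists at an unadjusted p under 0.05. Its test for change in either direction called 4, RNA binding and splicing factors, innate immune effectors, the insulin-like pathway and moulting (fry adjusted p = 5.23e-06, 0.00319, 0.0132 and 0.0487). The RNA binding list holds tdp-1, the mutated gene, as its only changed member, and ins-7 is the only changed insulin-like member. Neither list was tested without that gene, so their calls do not show a shift of other members. With the 3' minus 5' covariate camera called 10 lists at its preset correlation, 5 of them in the same direction as without it, and 0 with an estimated correlation. Leaving out single arrays also brought calls at the preset correlation to 10 lists not called with all 6, among them the endoplasmic reticulum unfolded protein response without wild-type replicate 2 or mutant replicate 2 (camera adjusted p = 0.00233 and 0.0212), mitochondrial respiration without the same 2 arrays (0.000137 and 0.0259) and intestinal genes without wild-type replicate 1 or mutant replicate 3 (0.00529 and 0.00858).

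Genes of moulting, the shedding and renewal of the cuticle between larval stages, fell as a set. Their median difference was -0.40 over 33 measured members, 29 of them lower in the mutant (camera adjusted p = 2.46e-16; adjusted p = 0.453 with an estimated correlation). None of the 33 passed on its own over all probe sets, and 14 fell when adjusted over the list alone. The protease inhibitor gene mlt-11 differed by -1.37, mlt-9 by -1.16, noah-1 by -1.06 and wrt-2 by -0.78. The list mean of each mutant array, -0.18 to -0.35, lay below that of each wild-type array, -0.03 to 0.47 (exact permutation p = 0.1). The median slope of its members on the 3' minus 5' control difference at fixed genotype, which was not tested, was -0.17 per log2 unit, and with that covariate the list median was -0.32 (camera adjusted p = 1.19e-09; adjusted p = 0.823 with an estimated correlation). Cuticle collagens fell as a set by less, with a median of -0.11 over 148 members (camera adjusted p = 0.000789; adjusted p = 0.688 with an estimated correlation). Among them col-41 fell, 1 of 148 over all probe sets and 1 adjusted over the list alone, while col-90 differed by -1.92 and dpy-8 by -1.09 without passing. The median collagen slope on the 3' minus 5' difference was -0.23, and with the covariate the median was 0.033 (camera adjusted p = 0.682). The collagen call was lost without wild-type replicate 3 (-0.02) or mutant replicate 3 (-0.03; camera adjusted p = 0.617 and 0.115), and the median was -0.22 without wild-type replicate 2.

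Innate immune effectors rose as a set. The median difference of 41 members was 0.25, with 30 higher in the mutant (camera adjusted p = 5.9e-05; adjusted p = 0.453 with an estimated correlation). The lectin gene clec-60 rose over all probe sets, and 9 members rose and 2 fell when adjusted over the list alone. Other lectin genes, clec-70 at 1.70 and clec-86 at 1.49, were higher without passing over all probe sets, and the antibacterial factor gene abf-2 was lower, at 4.11 against 5.11 (limma adjusted p = 0.0644). All 3 mutant list means, 0.12 to 0.21, lay above the wild-type ones, -0.23 to -0.07 (exact permutation p = 0.1), and with the 3' minus 5' covariate the median was again 0.25 (camera adjusted p = 9.54e-05; adjusted p = 0.823 with an estimated correlation).

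The DAF-16 class II genes, known as genes that the FOXO factor DAF-16 keeps low, rose as a set with a median of 0.18 over 12 members (camera adjusted p = 0.029; adjusted p = 0.688 with an estimated correlation). No member passed over all probe sets, and 2 rose adjusted over the list alone, dod-19 at 0.92 and dod-23 at 0.78. The DAF-16 class I targets had a median of -0.09 over 24 members (camera adjusted p = 0.053), with mtl-2 at -0.84, ftn-1 at -0.50, sod-3 at -0.41 and C08E8.4 at 0.60, none of them passing, and 9 of the 24 higher. In the insulin-like pathway list, ins-7 rose, 1 of 40 members both over all probe sets and adjusted over the list alone, and the list median was 0.033 (camera adjusted p = 0.756). The class II call was lost without wild-type replicate 2, wild-type replicate 3 or mutant replicate 2, with medians of 0.27, 0.08 and 0.18 (camera adjusted p = 0.0735, 0.284 and 0.158), and the class I list passed without wild-type replicate 3 (-0.15, camera adjusted p = 0.00385) or mutant replicate 1 (-0.09, camera adjusted p = 0.0404).

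Markers of neurons, muscle and neuropeptides were called lower as sets by camera at its preset correlation of 0.01. List means per array overlapped between genotypes for muscle and neuropeptide genes (exact permutation p = 0.4 and 0.3). Their estimated correlations were 0.434 and 0.276. All mutant means of the neuron list lay below the wild-type ones (exact permutation p = 0.1). The 47 neuron genes had a median of -0.13 (camera adjusted p = 8.08e-05; adjusted p = 0.688 with an estimated correlation), with 3 falling adjusted over the list alone, among them the synaptic vesicle GTPase gene rab-3 at -0.71 and mec-17 at -0.87. The 35 muscle genes had a median of -0.22 (camera adjusted p = 0.000162; adjusted p = 0.688 with an estimated correlation), and the giant kinase gene unc-22 fell by 1.20 adjusted over the list alone. The 44 neuropeptide genes had a median of -0.16 (camera adjusted p = 0.00288; adjusted p = 0.688 with an estimated correlation), with flp-4 at -0.50 and nlp-1 at -0.57 and 0 passing either way. Over all probe sets 0 members of these 3 lists passed. The median slopes on the 3' minus 5' difference were -0.01 for neuron, -0.20 for muscle and -0.22 for neuropeptide genes, and with the covariate the medians were -0.08, -0.04 and -0.06 (camera adjusted p = 0.00784, 0.944 and 0.966, and for neuron genes 0.823 with an estimated correlation). The neuropeptide call was lost without wild-type replicates 1 or 3 or mutant replicate 3 (-0.10, -0.08 and -0.11, camera adjusted p = 0.183, 0.179 and 0.12) and the muscle call without wild-type replicate 3 (-0.09, camera adjusted p = 0.336), while without wild-type replicate 2 these medians were -0.35 and -0.40. The neuron call was kept whichever array was left out, at -0.08 without wild-type replicate 1.

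**Figure D2:**
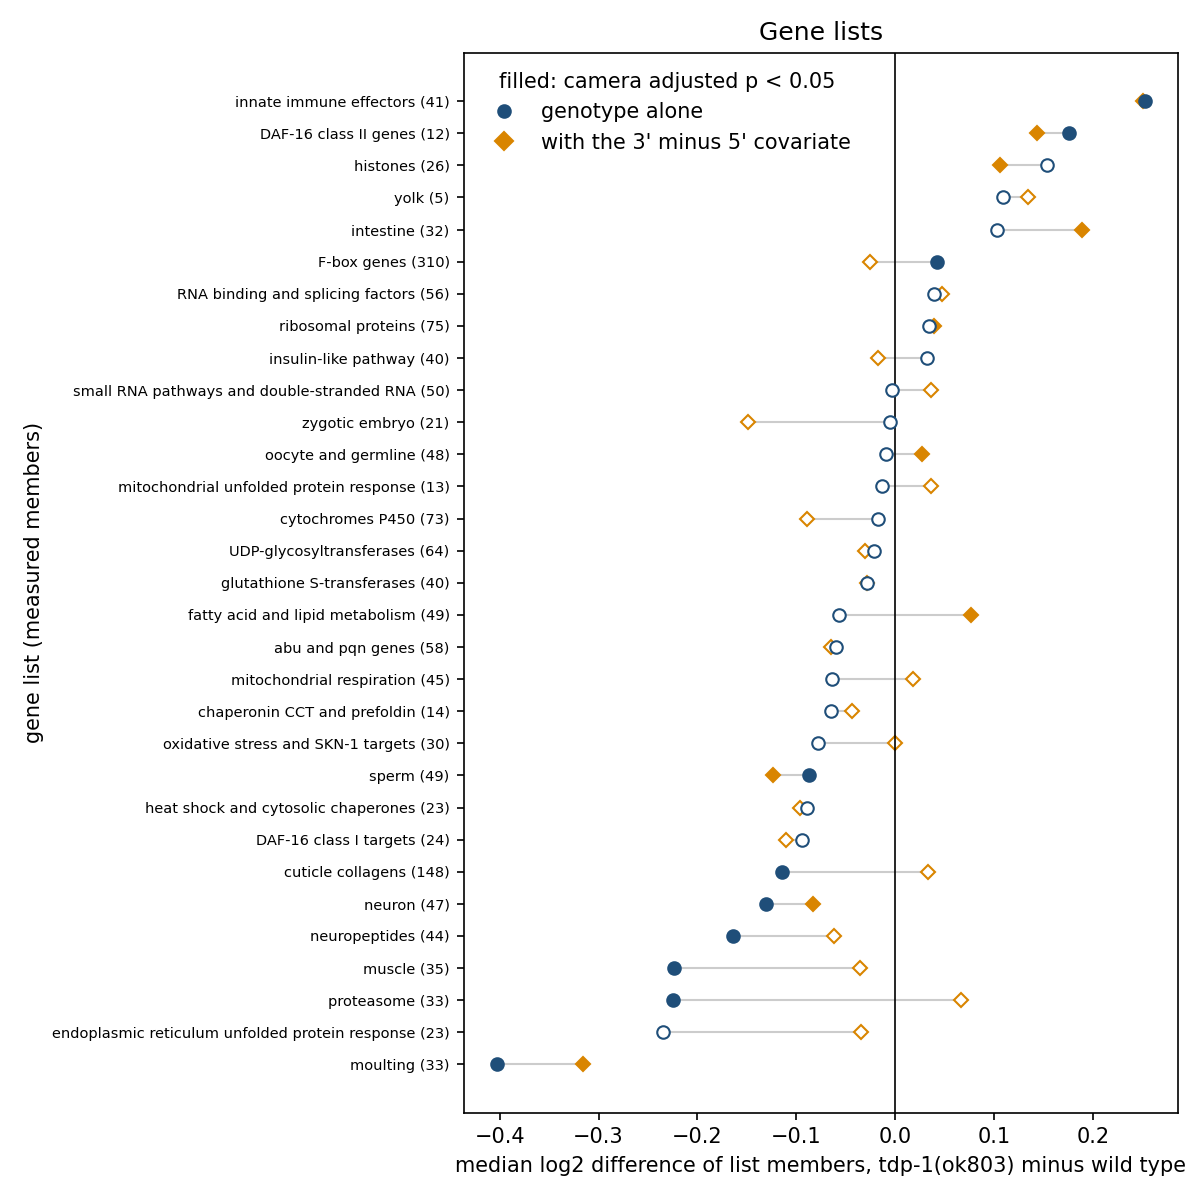
Median log2 difference, tdp-1(ok803) minus wild type (x axis), of the members of each of 31 gene lists (y axis, measured members in brackets), in the fit with genotype alone (blue circles) and with the 3' minus 5' covariate (orange diamonds); filled symbols passed camera with its preset correlation. Moulting lies lowest in both fits, at -0.40 and -0.32, and innate immune effectors highest, at 0.25 in both.

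Among genes of protein homeostasis, the proteasome list fell as a set, with a median of -0.22 and 28 of 33 members lower (camera adjusted p = 0.00288; adjusted p = 0.688 with an estimated correlation). No member passed, over all probe sets or adjusted over the list alone, and rpn-9 differed by -0.50, pas-1 by -0.44 and pbs-7 by 0.22. Proteasome genes had a median slope of -0.42 on the 3' minus 5' difference, and with the covariate the median was 0.067 (camera adjusted p = 0.0683). The list was not called without wild-type replicates 1 or 3 or mutant replicate 3 (-0.16, -0.13 and -0.05, camera adjusted p = 0.0837, 0.285 and 0.467), and its median was -0.44 without wild-type replicate 2 and -0.46 without mutant replicate 2. Medians were -0.09 for 23 heat shock and cytosolic chaperone genes, -0.06 for 14 chaperonin and prefoldin genes, -0.23 for 23 genes of the endoplasmic reticulum unfolded protein response and -0.01 for 13 of the mitochondrial one, with camera adjusted p of 0.16, 0.127, 0.065 and 0.37 and 0 members passing either way. Genes of the endoplasmic reticulum response had a median slope of -0.26 on the 3' minus 5' difference, and with the covariate their median was -0.03 (camera adjusted p = 0.948). The small heat shock gene hsp-16.41 had wild-type values of 8.68, 9.86 and 4.78 and mutant values of 6.49, 3.81 and 3.81, overlapping ranges with a difference of -3.07 ± 1.27 (SE). The mitochondrial list had a positive mean, 0.03, and a test direction upward against its negative median. Oxidative stress and SKN-1 targets had a median of -0.08 over 30 members (camera adjusted p = 0.138) and abu and pqn genes -0.06 over 58 (camera adjusted p = 0.138), none passing.

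In detoxification and metabolism lists, UDP-glycosyltransferases had a median of -0.02 over 64 members, glutathione S-transferases -0.03 over 40 and cytochromes P450 -0.02 over 73 (camera adjusted p = 0.567, 0.375 and 0.157). Over all probe sets 0 of these passed, and gst-24, at 1.33, rose adjusted over the list alone. In fatty acid and lipid metabolism, ech-9 rose, 1 of 49 members, and adjusted over the list alone ech-9 rose and acs-20 fell by 0.95. That list's median was -0.06 and its mean 0.02 (camera adjusted p = 0.601). Its sign turned with the fit. With the 3' minus 5' covariate the median was 0.077 and the list passed upward (camera adjusted p = 0.0239, and 0.823 with an estimated correlation). Without wild-type replicate 2 the list passed with a median of -0.08 (camera adjusted p = 0.0204). Mitochondrial respiration had a median of -0.06 over 45 members (camera adjusted p = 0.122), with 0 passing either way and a median slope of -0.15 on the 3' minus 5' difference.

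Lists of RNA binding, small RNA, ribosomal and histone genes were not called by camera. RNA binding and splicing factors, 56 genes with tdp-1 among them, had a median of 0.039 against a mean of -0.06 (camera adjusted p = 0.966; fry adjusted p = 5.23e-06 for change in either direction), and tdp-1 was the 1 member that changed, over all probe sets and adjusted over the list alone. The splicing factor gene rsp-3 differed by 0.56 and snr-5 by 0.32 without passing. Small RNA and double-stranded RNA genes had a median of -0.0036 over 50 members (camera adjusted p = 0.844), with alg-5 at 0.68 and ergo-1 at -0.52. Ribosomal protein genes had a median of 0.034 over 75 (camera adjusted p = 0.239) and histone genes 0.15 over 26 (camera adjusted p = 0.138), with 0 passing. With the 3' minus 5' covariate both lists passed, at 0.039 and 0.11 (camera adjusted p = 0.0239 and 0.0291), but not with an estimated correlation (0.823 for both). Histone genes also passed without wild-type replicate 1 (0.17, camera adjusted p = 0.0135). They are near-identical copies that 1 probe set may not tell apart. F-box genes rose as a set, with a median of 0.04 over 310 members, 194 of them higher and 0 passing on their own either way (camera adjusted p = 0.0342; adjusted p = 0.759 with an estimated correlation). With the 3' minus 5' covariate the F-box median was -0.03 (camera adjusted p = 0.762). The call was lost without wild-type replicate 3, where the median turned to -0.0070, or mutant replicates 1 or 3, where it was 0.044 and 0.016 (camera adjusted p = 0.617, 0.0731 and 0.0586), and the median was 0.11 without wild-type replicate 2 and 0.08 without mutant replicate 2.

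Among tissue and stage markers, sperm genes were called lower as a set by camera at its preset correlation. Their median was -0.09, with 40 of 49 lower and 0 passing on their own (camera adjusted p = 0.00311, and 0.688 with an estimated correlation of 0.413). The msp genes among them are near-identical copies that 1 probe set may not tell apart, so the 49 members are not 49 separate signals. List means per array overlapped between genotypes (exact permutation p = 0.4). Oocyte and germline genes had a median of -0.0093 over 48 members (camera adjusted p = 0.961), zygotic embryo genes -0.0049 over 21 (camera adjusted p = 0.37) and yolk protein genes 0.11 over 5 (camera adjusted p = 0.756), with 0 passing either way. The zygotic embryo median was -0.12 without wild-type replicate 3 and 0.05 without wild-type replicate 2. The yolk median was -0.014 without mutant replicate 2 and 0.17 without mutant replicate 3. The test direction of the oocyte list was upward against its negative median. Intestinal genes had a median of 0.10 over 32 members (camera adjusted p = 0.151), and adjusted over the list alone 3 rose, among them cpr-3 at 0.69 and asp-6 at 0.60, and 1 fell, mtl-2. The median intestinal slope on the 3' minus 5' difference was -0.19, and with the covariate the median was 0.19 (camera adjusted p = 1.79e-05; adjusted p = 0.823 with an estimated correlation). The sperm call was lost without wild-type replicate 3 or mutant replicates 1 or 2 (-0.05, -0.04 and -0.06, camera adjusted p = 0.4, 0.084 and 0.0986), and the median was -0.15 without wild-type replicate 1 and -0.17 without mutant replicate 3.

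**Figure D3:**
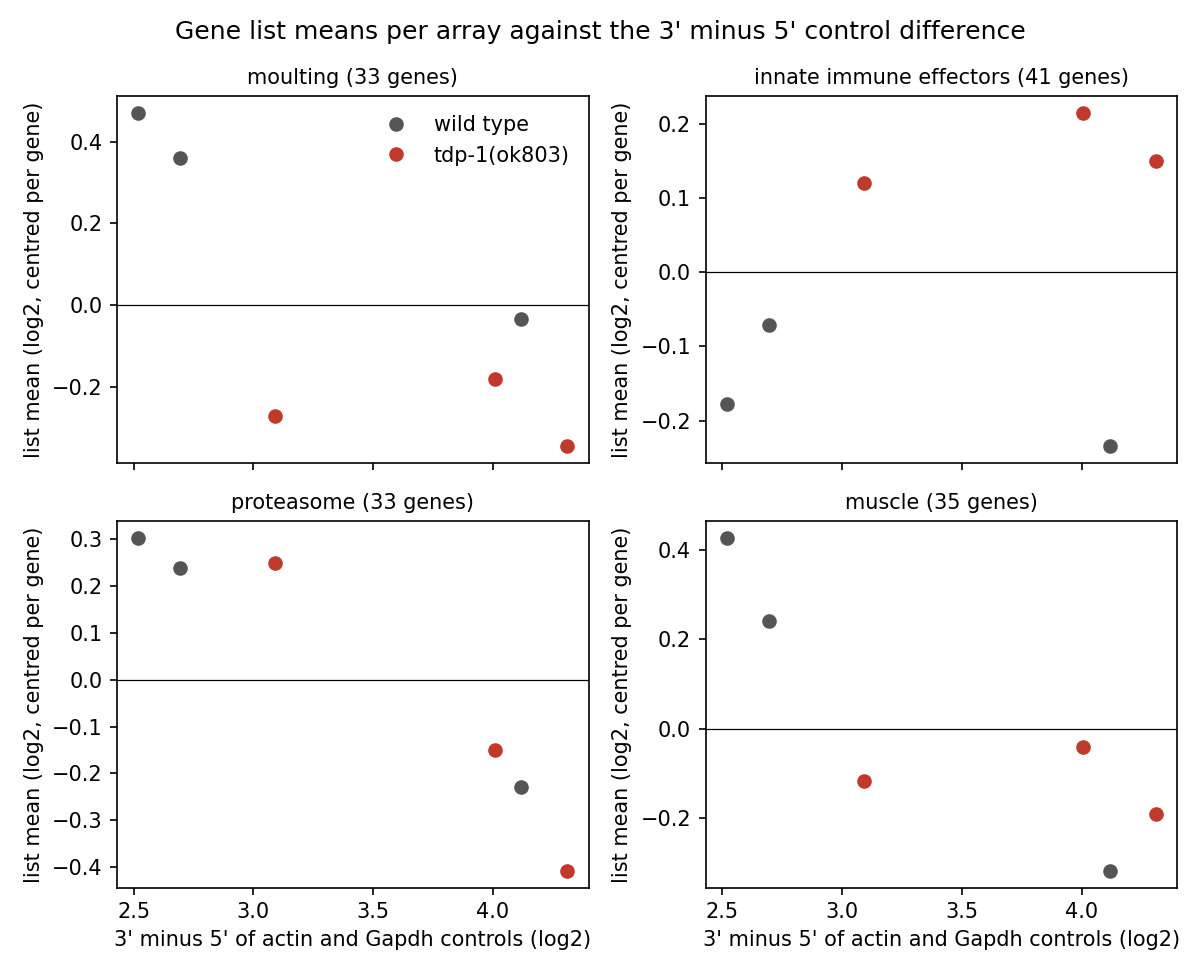
Mean of a list's genes on each array, in log2 units centred per gene (y axis), against the 3' minus 5' difference of the actin and Gapdh controls (x axis, log2), for 4 lists; grey points are wild type and red points tdp-1(ok803). For moulting and innate immune effectors all mutant means lie on one side of all wild-type means, while proteasome means range from 0.30 to -0.41 with the genotypes mixed.

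Genes near tdp-1 and on its chromosome were compared because an outcrossed strain can keep linked sequence around the selected allele. Besides tdp-1, clec-60 and pugs-2 lie on chromosome II, 2 called genes of 3012 there against 8 of 14063 elsewhere, where 1.76 would be expected (Fisher's exact p = 0.692, two-sided, odds ratio 1.17, 95% interval 0.121 to 5.85). Of the 10 nearest neighbours of tdp-1 in the WBcel235 gene table, 9 were measured and 0 passed, with differences between -0.10 (F44G4.5) and 0.25 (F44G4.3).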

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

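The covariate and the fit of 3 arrays were chosen after seeing the data, and causes were not tested unless given. The difference of the brighter tdp-1 probe set kept its direction and call under all alternatives except the unmoderated model (-3.97, adjusted p = 0.613), which called 0 probe sets, and 0 of 1.5-fold or more. The other tdp-1 probe set lost its call with that model too (-3.99, adjusted p = 0.613) and with the 3 arrays (-4.56, adjusted p = 0.114). Of the 13 changed probe sets, trend with robust and the dim filter kept 13 and quantile normalization 12. Equal array medians gave 7 (5 higher, 2 lower), the 0.01 threshold 6, the covariate 25, and the 3 arrays 2, with the lone mutant array assumed to vary like the others. Array weights gave 6291, and 1352 of 1.5-fold or more, but also 5350 for a split of mixed genotypes that gave 0 without weights. Leaving out single arrays gave 4 to 97. The replicate block gave 5 probe sets, and DAF-16 class I targets passed with it at -0.09. Deviations from the genotype means correlated at 0.05, -0.614 and -0.46 between equal numbers. No wild-type array correlated best with the mutant array of its own number. The axis that followed the 3' minus 5' difference also enters these deviations, so they cannot show whether equal numbers share a batch.

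Lists called numbered 4 (without wild-type replicate 3) to 14 when arrays were left out, 17 with the 3 arrays, and 0 with an estimated correlation, with or without the covariate, or with fry. Those 0 calls left medians at -0.40 (moulting), 0.25 (immune), -0.13 (neuron), -0.22 (muscle), -0.22 (proteasome), -0.16 (neuropeptides), -0.11 (collagens), -0.088 (sperm), 0.18 (DAF-16 class II) and 0.042 (F-box), with adjusted p of 0.453 to 0.759 and, for fry, 0.228 to 0.687. With the covariate, proteasome (0.067), collagens (0.033) and F-box (-0.026) reversed and lost the call, muscle (-0.036) and neuropeptides (-0.062) lost it, fatty acid (0.077) and oocyte (0.027) genes reversed and passed, and ribosomal (0.039), histone (0.11) and intestinal (0.19) genes passed. An estimated correlation with the covariate ended the calls of moulting (-0.32), immune (0.25), neuron (-0.083), sperm (-0.12) and class II (0.14) genes. F-box genes lost the call after quantile normalization (0.028), and class I passed with equal medians (-0.073). Array weights ended class II (0.12), F-box (0.057) and sperm (-0.064) and added endoplasmic reticulum (-0.34) and class I (-0.18) genes. Means of all probe sets added heat shock (-0.18), chaperonin (-0.23), endoplasmic reticulum (-0.28), class I (-0.18) and respiration (-0.085) genes. The 3 arrays ended proteasome (-0.0065), reversed oocyte (0.13) and added endoplasmic reticulum (-0.14), class I (-0.17), UDP-glycosyltransferases (-0.086), P450 (-0.073), RNA binding (0.071), respiration (-0.12) and abu and pqn (-0.11) genes.

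Moulting, immune and neuron genes kept their calls whichever array was left out. Lists gained calls without wild-type replicate 1 (P450, histones, intestine), wild-type replicate 2 (endoplasmic reticulum, oxidative stress, fatty acid, respiration, abu and pqn), wild-type replicate 3 (class I), mutant replicate 1 (class I, abu and pqn), mutant replicate 2 (endoplasmic reticulum, respiration, oocyte) and mutant replicate 3 (intestine). Ranges of medians were -0.57 to -0.33 (moulting), 0.23 to 0.29 (immune), -0.19 to -0.078 (neuron), -0.15 to -0.045 (class I), 0.085 to 0.27 (class II), -0.0070 to 0.11 (F-box), -0.060 to -0.017 (abu and pqn), -0.078 to 0.018 (P450), -0.33 to -0.10 (endoplasmic reticulum), -0.10 to 0.056 (fatty acid), 0.066 to 0.17 (histones), -0.14 to 0.0014 (respiration), -0.12 to -0.019 (oxidative stress), -0.46 to -0.053 (proteasome), -0.22 to -0.019 (collagens), -0.029 to 0.11 (intestine), -0.40 to -0.094 (muscle), -0.35 to -0.081 (neuropeptides), -0.098 to 0.026 (oocyte) and -0.17 to -0.041 (sperm). Another 55 of 558 list values changed sign with neither setting calling them. For the 11 changed genes, 74 combinations of gene and alternative lost the call and 102 kept it, with 0 reversed. The count of 2 genes on chromosome II held with dim genes left out. The unmoderated model was not run on lists, since camera moderates. Signal over background was not assessed, so what dim probe sets limit stays open.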

Other observations

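All tests of explanations in this part, and the gene families in it, were chosen after the results were seen.

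Members of 4 gene families picked afterwards lay lower in tdp-1(ok803). The 7 lipocalin-related lpr genes, none of them in the fixed lists, had a median of -1.15, with lpr-3 falling and lpr-4 at -1.19, lpr-5 at -1.18 and lpr-6 at -1.15 (camera adjusted p = 1.45e-11 over 6 families; adjusted p = 0.0343 with an estimated correlation). All 7 were lower as deposited and after quantile normalization, and 6 of 7 with equal array medians. Of them lpr-3, lpr-4, lpr-5 and lpr-6 share the sequence name stem W04G3 on chromosome X, and whether they vary independently was not tested. The 14 bus genes were all lower under each of these scalings, with a median of -0.26, bus-8B falling and bus-5 at -0.99 (camera adjusted p = 2.23e-09; adjusted p = 0.0343 with an estimated correlation). Hedgehog-related grd, grl and wrt genes had a median of -0.11 over 52 members, 36 of them lower and 8 held by the moulting list. Among those 8, wrt-1 differed by -1.18. Patched-related ptr genes had a median of -0.16, with 21 of 24 lower and 4 held by the fixed lists. Their camera adjusted p was 7.13e-06 and 8.97e-06, and 0.0343 and 0.046 with an estimated correlation. These p-values describe families picked because members stood out.

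Aspartyl protease genes lay higher, with a median of 0.22, 12 of 15 above 0 and 5 held by the fixed lists (camera adjusted p = 0.000614, and 0.0467 with an estimated correlation). Among them asp-12 rose, with asp-17 at 0.63 and asp-6 at 0.60. The genes asp-5, asp-6, asp-11 and asp-12 share the sequence name stem F21F8 on chromosome V, and whether they vary independently was not tested. Over all 220 C-type lectin genes, 8 of them held by the fixed lists, the median was 0.07 (camera adjusted p = 0.00318; adjusted p = 0.473 with an estimated correlation), and with the 3' minus 5' covariate it was -0.01 (camera adjusted p = 0.379).

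The largest axis of variation between arrays crossed the genotypes. The groups overlapped on that axis (exact permutation p = 0.3), so genotype alone did not order the arrays along it. Whether genotype contributes to the axis cannot be told, since 3 arrays against 3 allow no p under 0.1. RNA integrity or labelling is a candidate explanation, since the axis followed the 3' minus 5' difference of the controls at r = 0.973 over 6 arrays. Hybridization spikes followed the same axis (r = 0.964, exact permutation p = 0.00556), so a difference in overall hybridization stays open too.

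The lower moulting genes may reflect the mutation, the RNA or the mix of stages. RNA integrity cannot be told apart from the mutation: with the 3' minus 5' covariate the median was -0.32 and the list passed camera at its preset correlation, but not at its estimated correlation of 0.227 (adjusted p = 0.823). The covariate took the difference in list mean over the 6 arrays from -0.53 (95% interval -0.98 to -0.09) to -0.39 (-0.79 to 0.01). A smaller share of larvae among the mixed stages cannot be told apart from an effect within animals: oocyte and germline genes had a median of -0.0093 with members going both ways, and sperm genes fell while yolk genes did not pass. The oocyte list passed upward with the covariate (0.027, camera adjusted p = 0.0396, and 0.823 with an estimated correlation). Without mutant replicate 2 it passed with a median of -0.098 (camera adjusted p = 0.035). Stage was not recorded per sample, and how much of the sperm, oocyte or yolk signal came from larvae was not measured. The fall of sperm genes therefore counts neither for nor against a smaller share of larvae.

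The higher innate immune genes had a median of 0.25 with the 3' minus 5' covariate (0.2503 against 0.2527 without it). With it the list mean differed by 0.34 over the 6 arrays (95% interval 0.12 to 0.56). This argues against RNA integrity as the whole cause only as far as the actin and Gapdh controls measure it, in a fit of 6 arrays. With an estimated correlation camera did not call the list with the covariate (adjusted p = 0.823). Culture conditions that differed between strains, and background variants left after outcrossing, may also contribute and were not tested.

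With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. As many changed probe sets as the 13 observed came from 2 of the 10 splits, the real one included, and the highest other count was 1078. The same held for changes of 1.5-fold or more, with 13 against 851. That other split put wild-type replicates 1 and 3 with mutant replicate 2, the 3 arrays with the smaller 3' minus 5' difference, which points to a structure of the samples. As many lists as the 10 observed came from 7 of the 10 splits, with up to 16. The -log10 camera p of moulting (17.1 against at most 10.64 in the other splits) and of immune genes (5.419 against at most 3.898) was as large in 1 of the 10 splits, the real one. These 2 lists were picked because their camera p was smallest under the real grouping. The best list of each other split was not compared, so this rank lends no support. The moulting median itself was as large, at -0.41, in the split that put wild-type replicates 1 and 3 with mutant replicate 1.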
